A study of Mus musculus with 2 samples.

How the data were processed

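Small RNA from the intestine of 2 newborn mice was measured by microRNA sequencing, with 1 library per animal. Per the labels, the animals were pups of strain B6NCrl at postnatal day 0, both from the same pregnant female, and the RNA size range was below 30. The labels name the tissue as intestine without a segment, and the sex was not collected.

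The deposited values are raw read counts per miRNA gene, made by the authors against the mm10 assembly with the GENCODE M4 annotation, per the text that accompanies the counts. The aligner and the counting program were not given in the sources used here. Each library has 3 columns of counts, which from their sums hold reads on either strand, reads on the annotated strand and reads on the opposite strand. The deposited counts include 4 totals of reads that belong to no gene, and these stayed out of library sizes and tests. Reads that mapped to several places were 30.0% ± 0.382 of all reads (SD, n = 2) and were counted for no gene. Unmapped reads were 9.75% ± 0.562, and reads that mapped once outside miRNA genes were 2.32% ± 0.127. Reads on the opposite strand of a miRNA gene were 1.95% ± 0.0396, and 0 reads were ambiguous between genes. Since multi-mapped reads are lost, a miRNA made from several identical gene copies is undercounted, and its counted reads are those that reach outside the identical stretch or come from the other arm of the hairpin.

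Of 1973 genes in each library, 1894 had the same identifier in GENCODE M21 on GRCm38, the assembly that mm10 names in another style, and took their symbols, coordinates and host genes from there. The other 79 held 0 counts. A miRNA gene was placed from genes on its own strand that contain it. It was called exonic if it overlapped, by any length, an exon of any of their annotated transcripts, and intronic otherwise. Sequence that is intron in some transcripts and exon in others was thus called exonic. Counts on the annotated strand were the main measurement. CPM values were computed as counts per 1000000 counts in miRNA genes on that strand, and means and SDs were taken over the 2 pups. A gene was called detected with at least 10 counts in each library. A count of 0 allows up to 3 counts, which is 0.841 CPM in pup 1 and 0.640 CPM in pup 2. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

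The series has 1 group, so no comparison between groups exists. The pups were compared as libraries. Pearson and Spearman correlations of log2(CPM + 1) across detected genes describe their agreement, without p-values, because genes are not replicates. A chi-square of the counts over genes set the difference against counting noise, and the coefficient of variation came from edgeR's common dispersion with TMM scaling. Each detected gene was tested between the libraries with a 2-sided exact binomial test at the ratio of TMM effective library sizes, with Benjamini-Hochberg adjustment and a threshold of 0.05; this compares the 2 libraries and no conditions. Fold changes carry exact binomial 95% intervals. Summed counts of 19 lists of miRNA genes were given as shares. A list with at least 3 tested members was placed by its median log2 ratio, pup 2 over pup 1, among 10000 random lists of the same size drawn from 10 bins of mean expression, and called apart below percentile 2.5 or above 97.5. Pairs of miRNA genes from the same transcript, or close paralogs, were compared within libraries by edgeR's quasi-likelihood test with the pup as a block. Of 45 such pairs, 39 had both members among the genes used here and 38 had at least 10 counts of each member in each library.

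The lists, the pairs, the pairs of near-identical copies, the tests and the thresholds were fixed before the data were examined, as was the rule for the genes named. The rule takes the 20 genes of highest mean CPM, up to 4 highest members of each list, the pairs with the 6 largest ratios and 4 further pairs (Mir143 with Mir145a, Mir200b with Mir200a, Mir192 with Mir215 and Mir10a with Mir10b), the 5 genes furthest apart each way among those with at least 100 CPM, and the 4 copy pairs with the most counts. Genes named outside this rule were chosen after their values were seen, and the text says so. The alternatives tried were other scalings (DESeq2 size factors, total counts, upper quartile), other count minimums (1 and 100), a fold threshold of 1.5, a pseudocount of 0.5, counts that ignore strand, all reads as the denominator, the shares without the highest gene, each pup alone, and for the pairs limma, DESeq2 and a fit without the pup block. Alternatives chosen after seeing the data were opposite-strand reads given to the facing miRNA gene, the coefficient of variation, the chi-square and the Hox cluster list without the Mir196 genes, and lists without their farthest member. Lists of only 3 tested members, the miR-183 cluster and striated muscle, kept all their members there.

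The tests were tested on simulated data. In 314 simulated genes the library test called 4.39% of 114 unchanged genes, 86.6% of 67 genes changed 1.5-fold, 91.0% of 67 changed 2-fold and 100% of 66 changed 4-fold. That test allows for counting error only, so 4.39% is not the rate at which spread between animals beyond counting error is called. The random-list percentile called 6% of 50 unshifted lists and 86% of 50 lists shifted by 0.3 on the log2 scale. The pair test, in 20 simulated sets of 38 pairs, called 2.69% of pairs with equal members, 92.7% of pairs 2-fold apart and 100% of pairs 8-fold apart. The permutation test of genomic clusters called 0 of 20 simulated sets without a shared change and 13 of 20 with a shared change of SD 0.2. The software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, scipy 1.17.1, pandas 2.3.3 and numpy 2.4.6.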

Results

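MicroRNA sequencing measured the miRNAs of the intestine in 2 newborn B6NCrl littermates, called pup 1 and pup 2, with 1 library each. The libraries held 6375694 reads in pup 1 and 8373497 in pup 2. Of these, 3567658 and 4683939 were counted on the annotated strand of miRNA genes, a share of 55.9% ± 0.0138 (SD, n = 2). Every ± below is the SD over the 2 pups. Levels are given as CPM, the counts of a gene per 1000000 counts in all miRNA genes. In both pups, 314 of 1973 genes reached 10 counts, and 1301 had 0 counts in both. The design has no second group, so the values describe which miRNAs the newborn gut held and how far the littermates differed. Levels of different miRNAs also carry the sequence bias of small RNA capture, which the spread between the pups does not measure.

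Among the genes counted, Mir143 and Mir215 were the most abundant in the newborn intestine and together took 31.6% ± 0.148 of counts. Reads that mapped to several places, 30.0% of all reads, were counted for no gene. A miRNA with several gene copies may therefore rank too low here. Mir143, a miRNA of smooth muscle and fibroblasts, stood at 161103 ± 21783 CPM. Mir215, a miRNA of gut epithelium, stood at 154539 ± 23262 CPM, so their means were closer than the spread between pups: Mir143 was the higher of the pair in pup 1 and Mir215 in pup 2. Endothelial Mir126a followed with 52213 ± 3424 CPM. The 10 highest genes took 59.0% ± 0.119 of counts and the highest 7 took over 50%, while 46 genes held 90%. The miRNAs of the epithelium list among the 20 highest genes were Mir215, Mir429 (35301 ± 173 CPM), Mir192 (28894 ± 94.0), Mir200b (27514 ± 2056), Mir200c (22264 ± 1563), Mir194-1 (22021 ± 3749), Mir203 (11510 ± 597) and Mir194-2 (11483 ± 1483). Mirlet7g had 42069 ± 1174 CPM, Mir21a 34700 ± 2018, Mir26b 27147 ± 1054, Mirlet7i 26468 ± 3117 and Mir99a 22374 ± 1063. Mir22, Mir10a, Mir335, Mir23b and Mir30e completed the 20, from 19841 ± 667 down to 11881 ± 2345 CPM.

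On GRCm38, Mir143 lies on chromosome 18 from 61649196 to 61649258 on the minus strand, outside annotated genes of that strand. Mir215 lies on chromosome 1 from 185313581 to 185313692 and overlaps an annotated exon of 2010103J01Rik, and Mir194-1 lies in an intron of the same gene. Mir192 and Mir194-2 lie side by side on chromosome 19, outside annotated genes of their strand. Mir126a lies within Egfl7, an endothelial gene, on chromosome 2 and overlaps an exon of an annotated transcript there. It may be intronic in other transcripts of that gene. Mirlet7g lies in an intron of Wdr82, Mir26b in an intron of Ctdsp1, Mir30e in an intron of Nfyc, and Mir335 in an intron of the imprinted gene Mest.

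By fixed lists, miRNAs of intestinal epithelium took the most counts, 34.0% ± 3.37 over 12 genes, all 12 detected. Smooth muscle miRNAs followed with 16.6% ± 2.19, nearly all of it Mir143, since its list partner Mir145a had 4489 ± 85.4 CPM and Mir145b 0.494 ± 0.0945 CPM. Without Mir143 in the numerator and denominator the smooth muscle share was 0.536%. The mesenchyme list took 6.13% ± 0.242 over 9 detected genes of 10, led by Mir21a, Mir22, Mir145a (held by the smooth muscle list too) and Mir214 (1753 ± 163 CPM). The endothelium list rested on Mir126a alone, with 5.22% ± 0.342. In the mesenchyme list, Mir199a-2, Mir218-1 and Mir218-2, named after their values were seen, share runs of 22 to 27 nucleotides with a copy. Mir194-1 and Mir194-2 of the epithelium list share a run of 22. Reads that map to several places were counted for no gene, so the counts of both lists are lower limits and the distance between their shares is uncertain.

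**Figure D1:**
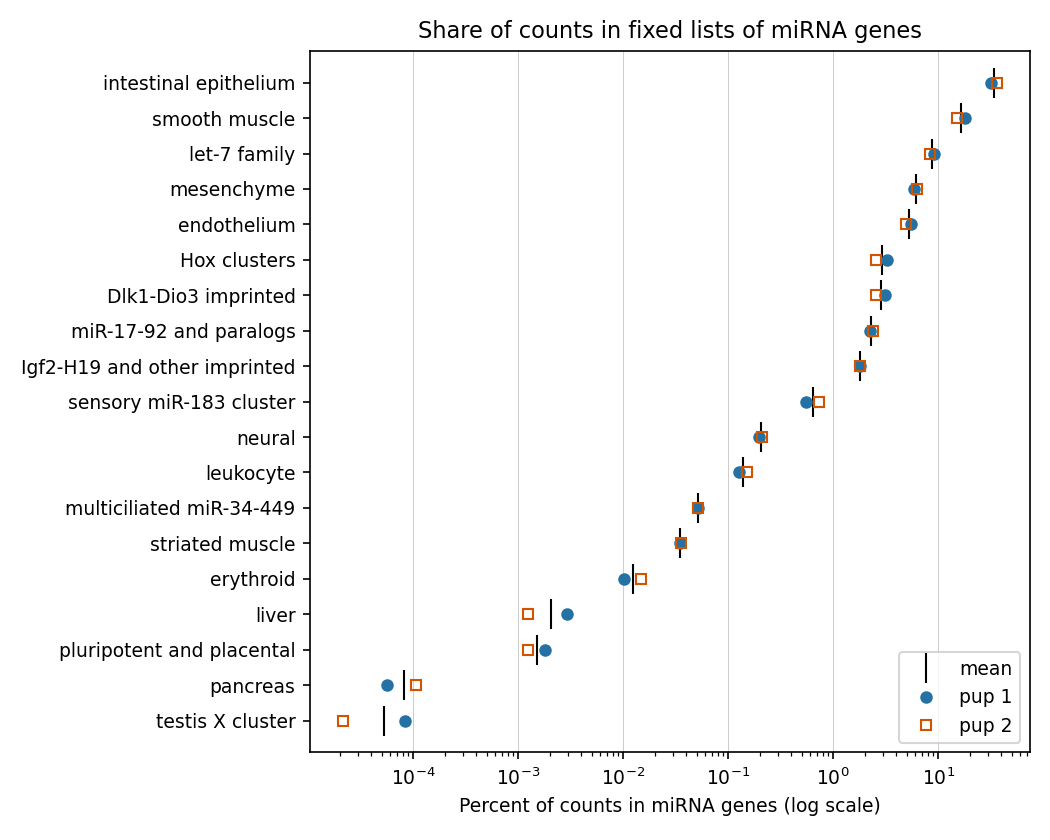
Share of counts in miRNA genes (percent, log scale) for each of 19 fixed lists, with pup 1 as filled circles, pup 2 as open squares and their mean as a vertical line. Intestinal epithelium leads with 34.0% ± 3.37 (SD, n = 2), and the pancreas and testis lists lie below 0.0002% in both pups.

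Blood, nerve and cell types of rarer epithelia left far fewer counts. The leukocyte list took 0.138% ± 0.0175, led by Mir342 (788 ± 134 CPM) and the myeloid miRNA Mir223 (396 ± 35.3), with Mir146 (95.4 ± 8.13) and the lymphocyte miRNA Mir150 (63.6 ± 2.40) below. That share was 0.235% when strand was ignored, because reads on the opposite strand of Mir142b, named for that after its counts were seen, then counted. The erythroid list took 0.0124% ± 0.00329, with Mir451a at 85.1 ± 35.1 CPM, Mir144 at 37.7 ± 2.93 and Mir486 at 1.63 ± 0.717. The neural list took 0.204% ± 0.0102 over 12 detected genes of 18, led by Mir137 (1052 ± 26.3 CPM), Mir7b (471 ± 69.3), Mir7-1 (148 ± 27.4) and Mir138-1 (138 ± 27.3). Mir7-1 and Mir138-1 each share a run of 24 nucleotides with a copy, and reads that map to several places were counted for no gene. The neural counts are thus lower limits, and how far this list lies below epithelium is uncertain. The miR-183 cluster of sensory and secretory cells took 0.639% ± 0.125, with Mir182 at 3482 ± 1025 CPM, Mir183 at 1572 ± 18.4 and Mir96 at 1337 ± 211. The list of miRNAs of multiciliated cells took 0.0516% ± 0.000560, with Mir34a at 268 ± 4.28 CPM, Mir34c at 196 ± 3.50, Mir449a at 43.2 ± 7.92 and Mir34b at 8.94 ± 1.55.

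Markers of tissues outside the gut were low. The striated muscle list took 0.0351% ± 0.000564, from Mir499 (234 ± 3.48 CPM), Mir208b (111 ± 8.71), Mir206 (5.30 ± 0.357) and Mir208a (0.354 ± 0.104). Liver Mir122 had 20.6 ± 11.7 CPM, from 103 counts in pup 1 and 58 in pup 2. The pluripotent and placental list had 15.2 ± 3.93 CPM in all, led by Mir302a (6.63 ± 0.926) and Mir302d (4.20 ± 0.803). The pancreas list had 0.814 ± 0.358 CPM and the testis X cluster list 0.527 ± 0.444 CPM, a few reads each and about the floor of 3 counts. A count of 0 was no evidence of absence for Mir1a-1, Mir133a-1 and Mir133a-2 of the muscle list or for Mir9-2, Mir124a-1, Mir124a-2, Mir124a-3 and Mir219a-2 of the neural list, which were named because they had 0 counts. Each shares a run of 22 to 33 nucleotides with another hairpin, and reads that map to several places were counted for no gene.

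Among miRNA families, let-7 took 8.73% ± 0.463 over 10 genes. Mirlet7g and Mirlet7i led it, ahead of Mirlet7d (8579 ± 185 CPM) and Mir98 (4788 ± 203). The miR-17-92 cluster and its paralogs, miRNAs of proliferating cells, took 2.30% ± 0.104 over 15 genes, led by Mir17 (7570 ± 557 CPM), Mir20a (4446 ± 458), Mir93 (3553 ± 302) and Mir106b (2815 ± 235). The imprinted Dlk1-Dio3 domain took 2.83% ± 0.388 over 41 detected genes of 47, led by Mir411 (6341 ± 1572 CPM), Mir127 (3762 ± 417), Mir379 (2942 ± 557) and Mir487b (2338 ± 109). The list of Igf2-H19 and other imprinted loci took 1.80% ± 0.0140, most of it Mir335 (15108 ± 211 CPM), with Mir296 at 1077 ± 18.9, Mir298 at 1002 ± 59.4 and Mir483 at 693 ± 9.12. MiRNAs of the Hox clusters took 2.90% ± 0.479, led by Mir10a (18882 ± 1385 CPM) and Mir10b (8771 ± 1939), with Mir196b at 1061 ± 1407 and Mir615 at 234 ± 8.93.

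Near-identical copies bounded what these levels mean. Mirlet7a-1 had 88.4 ± 14.4 CPM, Mirlet7a-2 80.1 ± 14.5, Mirlet7c-1 54.5 ± 3.29 and Mirlet7c-2 46.0 ± 7.64, all far below Mirlet7g and Mirlet7i; these 4 were named after their values were seen. The hairpins of these 4 share runs of 23 to 26 nucleotides with another hairpin, against at most 19 for Mirlet7g and Mirlet7i, so their counts are lower limits. The 4 copy pairs with the most counts were Mir194-1 with Mir194-2, Mir16-1 (1941 ± 155 CPM) with Mir16-2 (461 ± 71.4), Mir101b (1575 ± 87.7) with Mir101a (135 ± 10.7), and Mir92-1 (1074 ± 26.6) with Mir92-2 (66.0 ± 0.278). Their shared runs were 20 to 23 nucleotides, and reads that map to several places were counted for no gene. The counts of these genes are therefore lower limits, and the split of each pair between its genes is uncertain.

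Most paired miRNA genes of the same transcript or family held unequal counts, with ratios of the same sign in both pups. Mir17 exceeded Mir19a of its own cluster by 8.18 ± 0.14 on the log2 scale (290-fold; edgeR quasi-likelihood adjusted p = 0.00119), and Mir20a exceeded Mir19a by 7.41 ± 0.18 (adjusted p = 0.00119, edgeR). Mir130b exceeded Mir301b by 6.75 ± 0.33 (adjusted p = 0.00158), Mir143 exceeded Mir145a by 5.16 ± 0.17 (35.7-fold; adjusted p = 0.00146) and Mir322 exceeded Mir503 by 4.84 ± 0.07 (adjusted p = 0.00119). Mir23a was 25.4-fold above Mir27a, with a log2 ratio of Mir27a over Mir23a of -4.67 ± 0.11 (adjusted p = 0.00145). In the epithelial pairs, Mir200b was 9.53-fold above Mir200a (adjusted p = 0.00145) and Mir215 was 5.32-fold above its paralog Mir192 (adjusted p = 0.00348). Mir10a was 2.18-fold above Mir10b (adjusted p = 0.0124). Of 38 pairs tested, 30 differed, 22 with the first and 8 with the second member higher. Of the 30, 26 were over 2-fold apart and 10 over 8-fold. Some genes, Mir17 and Mir19a among them, are members of several pairs, so the pairs are not independent of each other. The ratio had the same sign in both pups in 38 of 38 pairs, with a median SD of 0.11 on the log2 scale. Of the 8 pairs that did not pass, Mir451a over Mir144 had the largest ratio, 1.11 ± 0.72 (adjusted p = 0.0921), and was named for that after the values were seen; it passed with DESeq2 (adjusted p = 0.000252) and with no pup block (adjusted p = 0.00242). Such ratios hold any difference in capture between the miRNAs, which is shared by both pups.

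**Figure D2:**
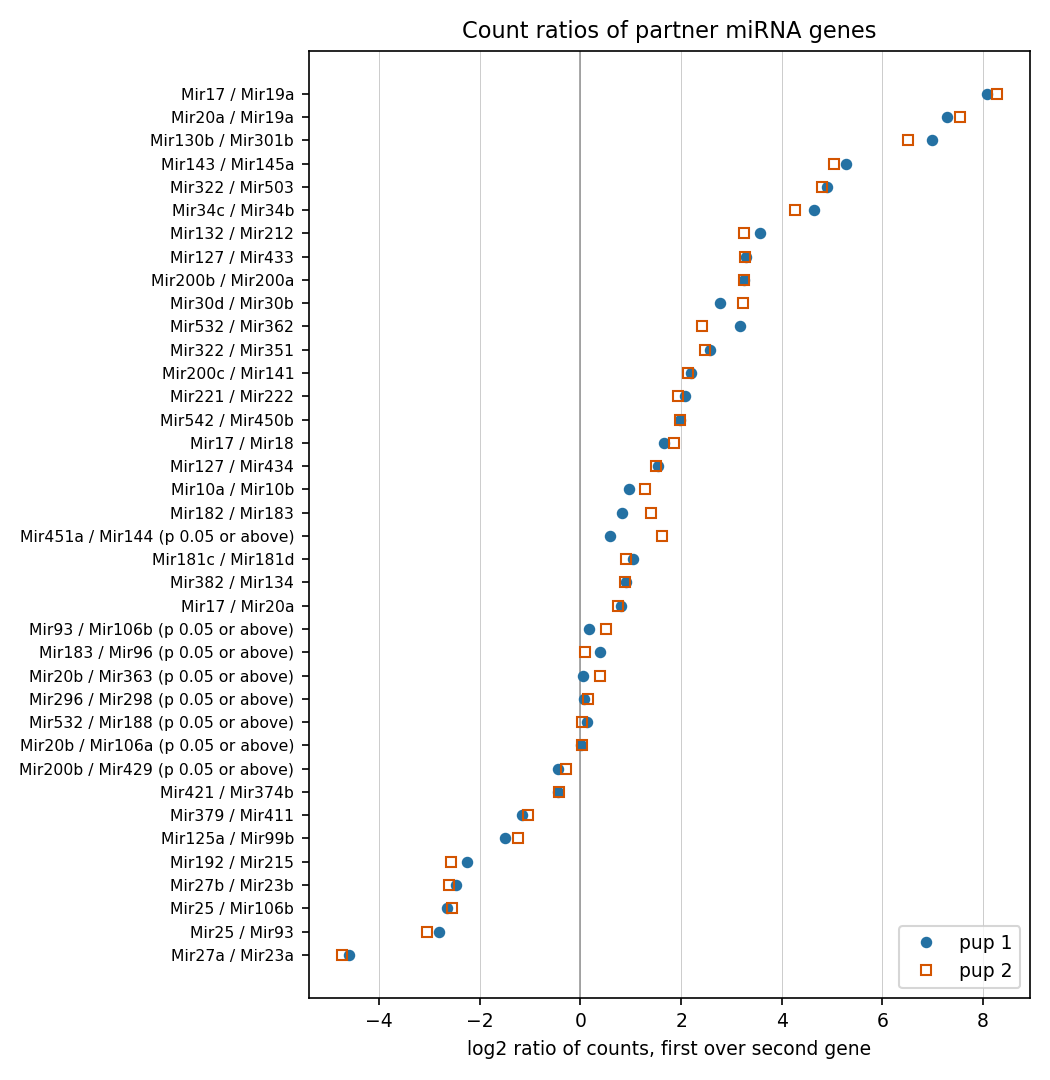
Log2 ratio of counts, first over second gene, for 38 pairs of partner miRNA genes, with pup 1 as filled circles and pup 2 as open squares. Pairs marked with p 0.05 or above did not pass edgeR's quasi-likelihood test after adjustment, and all 38 ratios have the same sign in both pups.

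Of the genes tested, Mir196b and Mir196a-2 stood furthest apart between the littermates. Mir196b, which lies in a Hox cluster, had 7337 counts in pup 1 and 310 in pup 2, which was 30.2-fold higher in pup 1 (95% interval 26.9 to 33.9, exact binomial) and a log2 ratio of -4.91, pup 2 over pup 1. Its relative Mir196a-2 in another Hox cluster had 272 and 35 counts, 9.90-fold higher in pup 1 (6.95 to 14.5, adjusted p = 4.24e-59, exact binomial test). Mir196a-1 had 16 and 3 counts, and both genes were named after their values were seen. Their hairpins share a run of 22 nucleotides, and reads that map to several places were counted for no gene. The counts of both are therefore lower limits. Across 314 genes Pearson's r was 0.993 and Spearman's rho 0.991, and the median absolute log2 ratio was 0.18. The coefficient of variation between the pups was 18.4%, and 10.6% without the Mir196 genes.

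Single genes other than these differed modestly. Among genes of at least 100 CPM, the lowest in pup 2 after Mir196b were Mir411 with a log2 ratio of -0.47, Mir10b with -0.41, Mir28a with -0.40 and Mir5099 with -0.38. The highest were Mir362 with 0.70, Mir182 with 0.65, Mir181b-2 with 0.61, Mir671 with 0.57 and Mir1981 with 0.47. All 10 passed the exact binomial test. Mir181b-2 shares a run of 26 nucleotides with a copy, so its counts are lower limits. Of 314 genes, 129 differed between the libraries, 67 higher and 62 lower in pup 2 (51.9% higher). That split was 53 to 74 (41.7%) with total-count scaling and 84 to 46 (64.6%) with upper-quartile scaling, so the direction of small differences depended on scaling. Only 6 genes were over 2-fold apart: Mir196b, Mir196a-2, Mir122 (2.26-fold; adjusted p = 1.76e-06) and Mir1247 were higher in pup 1, and Mir1198 and Mir8112 were higher in pup 2. Of these, Mir1247, Mir1198 and Mir8112 were named after their values were seen. At a minimum of 100 counts in each library 1 of the 6 was left, and over any gene with a count 9 were over 2-fold apart. The chi-square of the counts was 182 per degree of freedom, 155 without the Mir196 genes and 85.5 over any gene with a count; at this depth it sets the difference between separate animals against counting noise alone. These tests compare the libraries of 2 animals and contain no replicate of either.

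**Figure D3:**
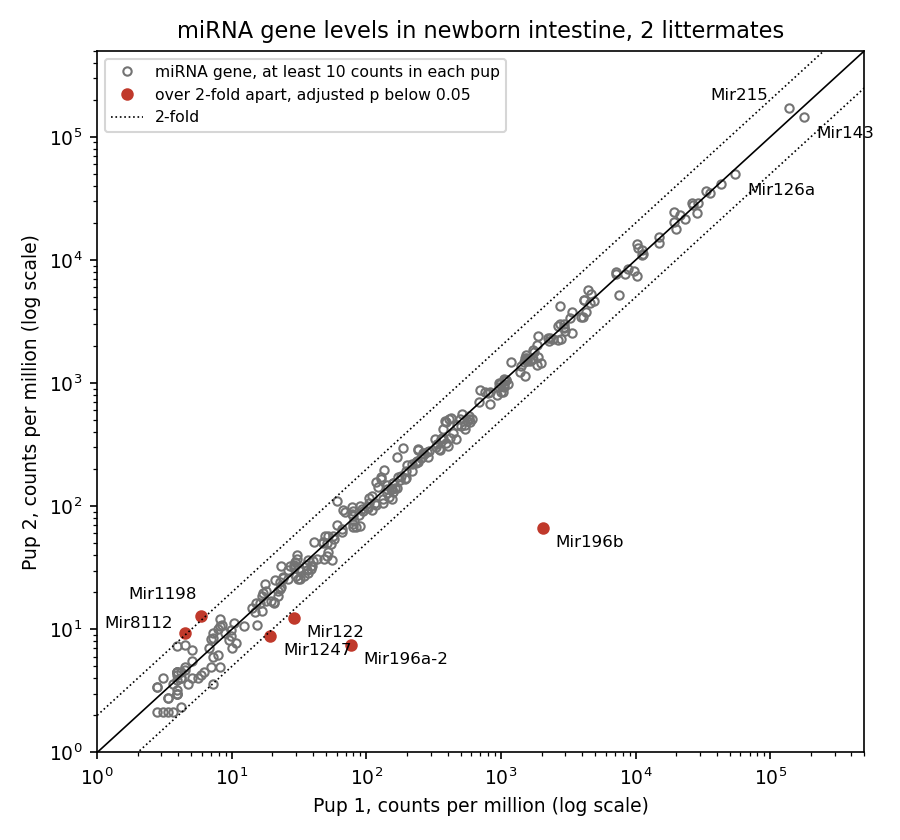
CPM of 314 miRNA genes in pup 2 against pup 1 (both log scale), with the diagonal solid and 2-fold lines dotted. Filled points are the 6 genes over 2-fold apart in the exact binomial test, with Mir196b farthest from the diagonal at 30.2-fold higher in pup 1.

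By list, epithelial miRNAs were higher in pup 2, except 2 of 12, Mir429 among them, that fell just below 0 with total-count scaling, and miRNAs of the Dlk1-Dio3 domain had a lower median. The Hox clusters had a lower median too, which moved inside the random range without the Mir196 genes. All 12 epithelial genes were called higher in pup 2, with a median log2 ratio of 0.19, above all 10000 random lists, for instance Mir215 with 0.35, Mir200b with 0.20, Mir192 with 0.05 and Mir429 with 0.03. With total-count scaling 9 of the 12 were called higher and 0 lower. The 3 genes of the miR-183 cluster were called higher, with a median of 0.37 at percentile 99.8 (Mir182 0.65, Mir96 0.37, Mir183 0.07), and Mir183 did not pass with total-count scaling. In the Dlk1-Dio3 domain 18 of 41 genes were called lower, 1 higher and 22 neither, with a median of -0.15, below all random lists, for instance Mir411 with -0.47, Mir379 with -0.35, Mir127 with -0.18 and Mir487b with -0.05, which did not pass with upper-quartile scaling. Of 5 Hox cluster genes 4 were called lower and Mir615 (-0.04, and above 0 with upper-quartile scaling) was not, with a median of -0.41, below all random lists; Mir10a had -0.11. Without the Mir196 genes the Hox median was -0.11 at percentile 6.13, inside the random range. Only 3 genes were then left, and the random range was wide, from -0.18 to 0.39. The Hox median was -1.60 with any gene that had a count. Without its farthest member it was -0.26 at percentile 0.25, still outside the random range. The random lists treat genes as independent, which was not established for genes of the same cluster.

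The leukocyte list had a median of 0.22 at percentile 97.7, with 2 of 5 genes called, Mir342 with 0.39 and Mir223 with 0.22. It moved inside the random range with any gene that had a count (percentile 82.4), with strand ignored (97.3) and without its farthest member (97.3). The other 7 lists tested lay inside it: striated muscle (percentile 83.8, 0 of 3 genes called), mesenchyme (39.8, with 2 higher and 1 lower of 9), neural (91.3, with 4 higher of 12), let-7 (68.4, with 4 higher and 3 lower of 10), miR-17-92 and paralogs (72.8, with 5 higher and 1 lower of 15), Igf2-H19 and other imprinted loci (50.1, with 1 higher and 1 lower of 5) and multiciliated cells (62.5, with 0 of 4). The 4 let-7 genes called higher share runs of 22 to 26 nucleotides with another hairpin, so their counts are lower limits. The 3 called lower share at most 19. The small differences of these 7 lists depended on scaling. With total counts the calls were 3 higher and 4 lower for let-7, 2 higher and 3 lower for mesenchyme, 5 higher and 2 lower for miR-17-92 and paralogs, 3 higher for neural and 1 lower for multiciliated cells. With upper-quartile scaling they were 7 higher and 1 lower for let-7, where Mirlet7g went from called lower (-0.01) to called higher (0.03), 3 higher and 1 lower for mesenchyme, 2 higher for Igf2-H19 and other imprinted loci and 1 higher for striated muscle. Lists with fewer than 3 tested members had no percentile. Of their 8 tested genes, Mir143 had a log2 ratio of -0.23, Mir126a -0.09, Mir122 -1.18 and Mir451a 0.91, and these 4 passed. Mir145a with 0.00398, Mir144 with -0.12, Mir302a with -0.24 and Mir302d with -0.35 did not, with adjusted p from 0.686 to 0.905 in the exact binomial test, though Mir145a was called lower with total counts (-0.04) and higher with upper-quartile scaling (0.05). Counts adjusted over the list alone were equal to these in each of the 19 lists.

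**Figure D4:**
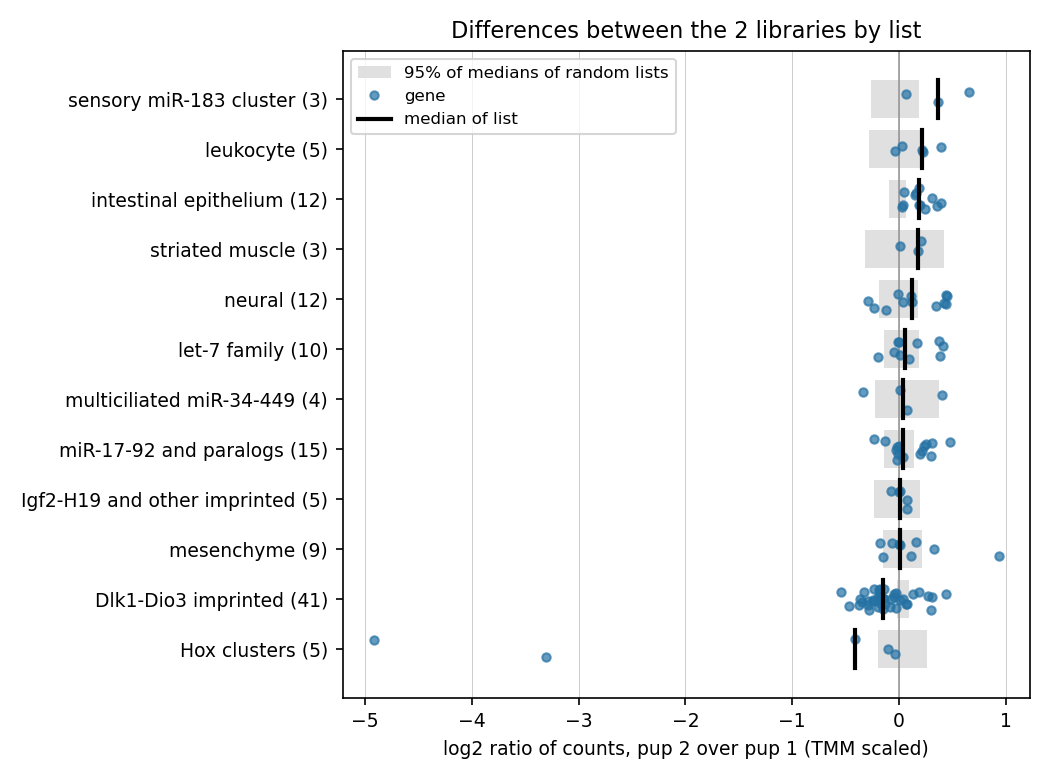
Log2 ratio of counts, pup 2 over pup 1 with TMM scaling, for the genes (points) of 12 lists, with the number of genes in parentheses, the list's median as a black line and the central 95% of medians of 10000 matched random lists as a grey band. The medians of 5 lists lie outside their band, with Hox clusters lowest at -0.41 (and inside the range of random lists when the Mir196 genes are left out) and the miR-183 cluster highest at 0.37.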

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

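The tests of explanations in this part were all chosen only after the results they bear on had been seen.

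Counts on the opposite strand of miRNA genes lie outside the main measurement, and with no control samples they stand out because they exceed the 3 counts that a count of 0 allows. Summed over both pups, the genes with at least 100 such counts in each library were Gm25301 with 191276, Gm24083 with 28450, Gm25927 with 18077, Gm25252 with 13724, Gm24321 with 10253, Mir142b with 8746, Mir299b with 6660, Mir497b with 4361, Gm25750 with 3646, Gm24111 with 1132, Mir203 with 558 and Mir3074-1 with 273. Gm25301, on chromosome 18 from 61397813 to 61397925, held 66.6% of all opposite-strand counts.

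Reads that lost their strand in the library are argued against, since over the 100 highest miRNA genes the opposite strand held only 0.00851% of the counts of the annotated strand. A candidate explanation is a miRNA gene on the other strand that was not among the genes counted. Of all opposite-strand counts, 99.8% lay in genes that overlap, by at least 20 bp, an M21 miRNA gene of that strand without counts of its own here, and this held for 11 of the 12 genes above, with Mir203 the exception. The facing gene of Gm25301, named after its counts were seen, is Mir378a, on chromosome 18 from 61397835 to 61397900 on the minus strand. With 1 group of samples, no biological explanation was tested.

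Mir196b and Mir196a-2 were lower in pup 2. Mir196a-2 counts that are only misplaced reads of Mir196b, whose closest window of 22 nucleotides has 1 mismatch, are argued against, because a fixed share of misplaced reads gives the same ratio in both pups. Mir196a-2 had 3.71 counts per 100 of Mir196b in pup 1 and 11.3 in pup 2 (Fisher's exact test, p = 1.21e-07). That p covers counting error only, since reads are not independent molecules and each pup had 1 library. Tissue of another organ carried into pup 1 stays open: the summed counts of the 5 lists of other tissues had a log2 ratio of -0.01 (-0.00993), but 90.8% of them were of the striated muscle list, the liver list had -1.18 and the pluripotent and placental list -0.49, and tissues without a list were not measured. Mir196a-2 counts that are misplaced only in part stay open as well. No biological explanation was tested, since the series has 1 group and the labels name no segment of the gut.

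The epithelial list had a higher and the Dlk1-Dio3 list a lower median in pup 2. Over 4 scalings the epithelial median stayed between 0.14 and 0.23 and the Dlk1-Dio3 median between -0.20 and -0.11. The median nearest 0 was -0.11 (-0.112). The alternative scalings moved the ratios by only -0.04 to 0.04, so these medians could not have changed sign under them. A scaling moves all genes alike and leaves the gap of 0.339 between the list medians. Scaling of the libraries as the whole cause is therefore argued against. A lower share of mesenchyme, smooth muscle and vessels in pup 2 could give the same pattern, but the members of those lists went both ways, from -0.23 for Mir143 to 0.93 for Mir218-1 (14 and 34 counts, named after its value was seen), with a median of -0.00168, which decides nothing. A difference between the pups in maturity or in the part of the gut taken was not tested, since the labels give no such group.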

How the results depend on the processing

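Of the alternatives in this part, opposite-strand reads given to the facing gene, the coefficient of variation, the chi-square and the Hox clusters without the Mir196 genes and lists without their farthest member were chosen only after the data had been seen. No list past its threshold and no named pair changed direction in any alternative run. For these lists the other scalings could not have changed the direction, since they moved the ratios by only -0.04 to 0.04. For the pairs the unchanged direction says little as well, since the ratio came from the same counts under each test and count minimum. Only ignoring strand, giving opposite-strand reads to the facing gene or taking each pup alone could have changed it. The medians of 4 lists inside the random range changed sign with total counts: mesenchyme (-0.04), miR-17-92 and paralogs (-0.01), Igf2-H19 and other imprinted loci (-0.04) and multiciliated cells (-0.00194); those of mesenchyme and Igf2-H19 also did with any gene that had a count. Genes lower in pup 2 outnumbered those higher with total counts (74 to 53) and with any gene that had a count (61 to 59). The number of detected genes was 536 at a minimum of 1 count. The share of the 10 highest genes was 57.0% with strand ignored, 57.0% with opposite-strand reads given to the facing gene and 53.8% without the highest gene; each change follows from the counts added or removed. Pearson's r was 0.990 at a minimum of 100 counts, and Spearman's rho was 0.986 there and 0.925 over any gene with a count. The coefficient of variation was 10.6% without the Mir196 genes, and the chi-square per degree of freedom was 85.5 over any gene with a count. Genes over 2-fold apart numbered 9 over any gene with a count, 1 at a minimum of 100 counts and 10 at 1.5-fold, as the genes tested or the threshold changed. Genes that differed between the libraries numbered 120 to 136 over 6 alternatives against 129. Partner pairs that differed numbered 25, at a minimum of 100 counts where fewer pairs could be tested, to 35, with opposite-strand reads given to the facing gene, against 30.

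With all reads as the denominator, the list shares were 19.03% for epithelium, 9.26% for smooth muscle, 3.43% for mesenchyme, 2.92% for endothelium, 4.89% for let-7, 1.29% for miR-17-92 and paralogs, 1.58% for Dlk1-Dio3, 1.01% for Igf2-H19 and other imprinted loci and 1.62% for Hox clusters. Without Mir143, the highest gene, they were 40.5%, 0.536%, 7.30%, 6.23%, 10.4%, 2.74%, 3.38%, 2.14% and 3.46% in the same order. The Igf2-H19 share was 1.74% with strand ignored and 1.74% with opposite-strand reads given to the facing gene. The leukocyte difference between the libraries fell inside the random range with any gene that had a count (median 0.11), with strand ignored (0.19) and without its farthest member (0.22); the cause was not tested. The Hox difference fell inside the random range without the Mir196 genes (median -0.11). The neural difference passed to percentile 97.8 with strand ignored. Each pup alone moved no share of a list or of the 10 highest genes by more than 1 SD, which 2 values cannot exceed, so this says nothing about stability. With 1 group there were no groups to pair; partner pairs were compared within pups, and 31 differed with no pup block. Depth limits the pancreas and testis lists, where a few counts decide the value.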

Other observations

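The grouping of genes into genomic clusters was chosen after the ratios of single genes had been seen, and its permutation test was set out before that test was run. By position, 133 of the 314 detected genes lay in introns of genes on their strand and held 28.8% of counts, 78 lay in exons and held 38.8%, and 103 lay outside genes of their strand and held 32.4%. Exonic genes were thus 24.8% of genes, with Mir215, Mir126a, Mir429 and Mir21a among them.

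Read at the level of the facing gene, the opposite-strand counts would place Mir378a at 23226 ± 480 CPM (SD, n = 2), which would be rank 11. Mir191 would have 3448 ± 2.57 CPM, Mirlet7e 2202 ± 121, Mir376a 1673 ± 106, Mir409 1242 ± 7.68 and the leukocyte miRNA Mir142 1054 ± 60.9. These genes were named after their values were seen.

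Of 227 genes with at least 100 counts in each library, 113 fell into 35 clusters of neighbours at most 10 kb apart on the same strand. Levels within a cluster spanned a median of 6.72-fold, and over 8-fold in 13 clusters. The hypothesis that neighbours on a shared transcript may change together between the pups was tested by the median SD of their log2 ratios, which was 0.156 over all clusters against 0.174 with genes permuted (one-sided permutation p = 0.229, 100000 permutations). Outside the Dlk1-Dio3 domain it was 0.168 in 31 clusters, against 0.166 permuted (one-sided permutation p = 0.539). The test gave no support to a shared change. It called only 13 of 20 simulated sets with a shared change of SD 0.2, so it leaves a shared change of that size or smaller open.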
